A study of Caenorhabditis elegans with 6 samples.

How the data were processed

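Gene expression was measured in whole mixed-stage embryos of Caenorhabditis elegans on 6 Affymetrix arrays, 3 of the mir-35-41(nDf50) mutant and 3 of wild type. Per the labels' protocols, worms grew on agar plates with added egg yolk and were shifted from 20 to 25 °C 24 hours before harvest, embryos were freed with hypochlorite, total RNA was extracted with Trizol, and biotin-labelled RNA was made with a single round of amplification. Some description fields of the labels speak of embryonic stages defined by nuclear cycles and pole cells, which are terms of insect development. These stages are not ones of worm embryos, so the fields were not used, and the stage was taken from the source and stage fields.

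The authors deposited a table of normalized intensity values on a linear scale, 1 column per array. Per the submitters' processing notes, Affymetrix Expression Console was used. Its version, the summarization algorithm and the background correction are not given in the sources used here. The series matrix that the authors deposited holds log2 values, and these equal the log2 of the linear table within 5.66e-06, so it is not an independent alternative. Lowest intensities per array were 9.34 to 10.2 and quartiles were close between arrays (29.6 to 30.6 for the lower and 520.2 to 548.8 for the upper), which shows that the arrays had been put on a common scale. Such a scale hides any change in the total amount of messenger RNA per embryo, and a summary of probes can compress large differences.

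The analysis started from log2 of the linear table with no pseudocount, since all values were above 0. Of 22625 probe sets, 77 controls were left out and 22548 were tested, with no filter on dim ones. By the gene columns of the deposited table, 20732 probe sets had 1 gene, 756 had several and 1060 had none. For each of 17337 genes the probe set with the highest mean over the 6 arrays was used, among those with 1 gene. Symbols in the table are old, and some cells hold a protein class or a date made by a spreadsheet, so names were updated through a gene table of assembly WBcel235, with the sequence name in the identifier column as a fallback. This matched 16832 genes, 13298 by symbol, 2947 by locus tag and 598 by sequence name in the identifier column, with some genes counted by more than 1 route, and 505 kept the name of the file. The gene table served for names and for the chromosome of each gene, and no coordinates were used. Of the genes past the threshold 119 had several probe sets, and 2 of these had a probe set of opposite sign, none of those past the threshold. Probe sets of the kinds that Affymetrix marks as shared made up 29.4% of the genes past the threshold and 25.3% of all genes. Of the named genes past the threshold outside the largest rises and falls, nlp-29, lys-7, fat-6, dpy-5, dpy-8, che-14, hsp-60, egl-21, tbb-4 and ced-7 have such probe sets.

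Mutant and wild type were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, 2-sided, without covariates, with Benjamini-Hochberg adjustment over all probe sets or over all genes, and a threshold of 0.05. Gene lists were written from textbook knowledge before the data were examined, as were the tests, the rule for named genes and the alternatives unless stated otherwise. However, nhl-2 and sup-26 are known from earlier work on the same microRNA family, possibly on these samples. Of 28 lists, 26 had at least 3 measured members. The respiratory chain genes of mitochondrial DNA had no probe sets, and the list of the deleted locus had 1 measured gene. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with the directional test of fry, each adjusted over the lists. X-linked and autosomal genes were compared with camera in the same way. The planned test of messenger RNAs with matches to the mir-35 seed was not run, because no genome or untranslated region sequences were used here.

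The genes named are the measured genes of the locus and of the earlier targets, the 10 largest rises and 10 largest falls among genes past the threshold whose arrays did not overlap between groups, and, from each list, up to 4 members past the threshold by size of change, or the 2 largest by value where none passed. Genes of the msp and his families are named only as families. A part of the rule for genes with seed matches did not apply.

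The alternatives were the replicate number as a block, each array left out in turn, the series matrix table, quantile normalization, median centring, leaving out the dimmest 25% or 50% of probe sets, a pseudocount of 16, an intensity trend with a robust fit, array weights, a 2-fold minimum, a plain equal-variance test, the mean of all probe sets of a gene, and the other set tests. One alternative, without both arrays numbered 1, was added after the data were seen. The steps were tested on simulated data with independent normal noise, whose spread was drawn from the distribution that limma fitted to these arrays. In 10 runs over 22548 probe sets with 200 changed per run, 74.4% of 2-fold and 96% of 4-fold changes were recovered, and 5.17% of calls were false. The model behind limma holds in such data, which lack correlated genes and outlying arrays. These rates therefore check the steps and are not error rates of the calls on the real arrays. The 77 control probe sets gave no call with limma (3 had an unadjusted p under 0.05). The comparison of dim genes with the yeast control probe sets was added after the data were seen, and the deposited tables hold no detection calls. The 3′ minus 5′ log2 signal of the actin controls, a sign of RNA quality, was 0.32 ± 0.05 in the mutant and 0.41 ± 0.09 in wild type (SD, n = 3 each), that of the glyceraldehyde phosphate dehydrogenase controls was -0.08 ± 0.09 and -0.11 ± 0.08, that of the catalase controls 0.46 ± 0.03 and 0.36 ± 0.18, and that of the ubiquitin controls 3.05 ± 0.01 and 2.97 ± 0.09. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.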

Results

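RNA from whole mixed-stage Caenorhabditis elegans embryos was measured on 6 Affymetrix arrays. 3 arrays carried RNA of the mir-35-41(nDf50) mutant, which lacks the mir-35 to mir-41 cluster of microRNAs, and 3 carried RNA of wild type (N2). The mir-35 family is abundant in the early embryo, and its members act as repressors of messenger RNAs that hold a match to their shared seed. The labels describe the mutant strain as lacking nEx1187, an extrachromosomal array by its name. All cultures were moved from 20 to 25 °C 24 hours before embryos were isolated with hypochlorite. The median normalized intensity per array was 119, 127 and 127 for mutant replicates 1, 2 and 3, and 114, 121 and 121 for wild type replicates 1, 2 and 3. With 3 arrays per group, the number of arrays limits the precision. No label says that the replicates came from separate cultures, so every p-value measures only the spread between these samples, which may be technical.

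The first question was which transcripts differ between embryos with and without the microRNA cluster. In the mutant, genes for defence peptides and transthyretin-like proteins were among those that rose. Of 17337 genes with a probe set of their own, 637 passed the threshold, 525 higher and 112 lower in the mutant (limma, Benjamini-Hochberg adjusted p under 0.05). The median rise among those was 1.20 on the log2 scale, or 2.30-fold, and the median fall was -0.64, or 1.55-fold lower. At least a 2-fold difference was reached by 332 of the genes that rose and by 9 of those that fell. Higher genes made up 82.4% of the calls, and 69.8% when each array was centred on its own median. The balance depended on the arrays: 1247 rose and 724 fell without mutant replicate 1 (63.3% higher), 1782 rose and 1610 fell with array weights (52.5%), and 1597 rose and 1400 fell without both arrays numbered 1 (53.3%, a setting chosen after the data were seen). Of the 525 genes that rose, 121 had wild type means no higher than the brightest of 5 yeast control probe sets, which have no target in worms (3.75 to 5.42 in wild type). For 25 of these the mutant mean was also no higher than the brightest such control in the mutant (5.34), so neither group shows clear signal. The differences of the others may be understated. At the level of probe sets, 785 of 22548 passed, 639 higher and 146 lower.

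The largest rise was that of srlf-34, at 3.93 on the log2 scale (SE 0.39, n = 3 against 3, limma adjusted p = 0.00606). It was followed by nspe-7, of a nematode-specific peptide family, at 3.69, and by the transthyretin-like gene ttr-26 at 3.64. Y38E10A.14 rose by 3.63, and its 3 mutant arrays had an SD of 0.02 against 0.55 in wild type. A second transthyretin-like gene, ttr-21, had a difference of 3.49, and C53B7.3 rose by 3.47. The genes fipr-2, of a family related to fungus-induced proteins, C50F7.5, C54D10.3 and F16B4.4 rose by 3.46, 3.37, 3.36 and 3.33. The wild type means of ttr-21 and C54D10.3, 5.04 and 4.94, lay within the range of the yeast control probe sets, so their differences are at best lower bounds and their places in this order are open. The adjusted p-values of these 10 genes lay between 0.00329 and 0.0102. The probe sets of nspe-7 and Y38E10A.14 are of the kinds that Affymetrix marks as shared between transcripts, so related genes may contribute to their signal.

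The falls were led by srw-85, of a family of predicted chemoreceptors, at -1.91 (SE 0.13, n = 3 against 3, limma adjusted p = 0.00327), with a mutant mean of 4.64 that lay within the 3.73 to 5.34 of the yeast control probe sets, so the fall may be larger. F43G6.8 fell by 1.83 and C51E3.8 by 1.52, and C23H5.8 and dhgd-1 fell by 1.45 and 1.44. The gene cht-5, annotated as a chitinase in the deposited table as C51E3.8 is, fell by 1.41 on its brighter probe set. The other probe set of cht-5 gave -1.38. Y64H9A.2, T16G12.1, glit-1 and the F-box gene fbxb-48 fell by 1.32, 1.09, 1.02 and 0.97. The probe sets of F43G6.8, C51E3.8, C23H5.8, dhgd-1 and T16G12.1 are also of the shared kinds.

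**Figure D1:**
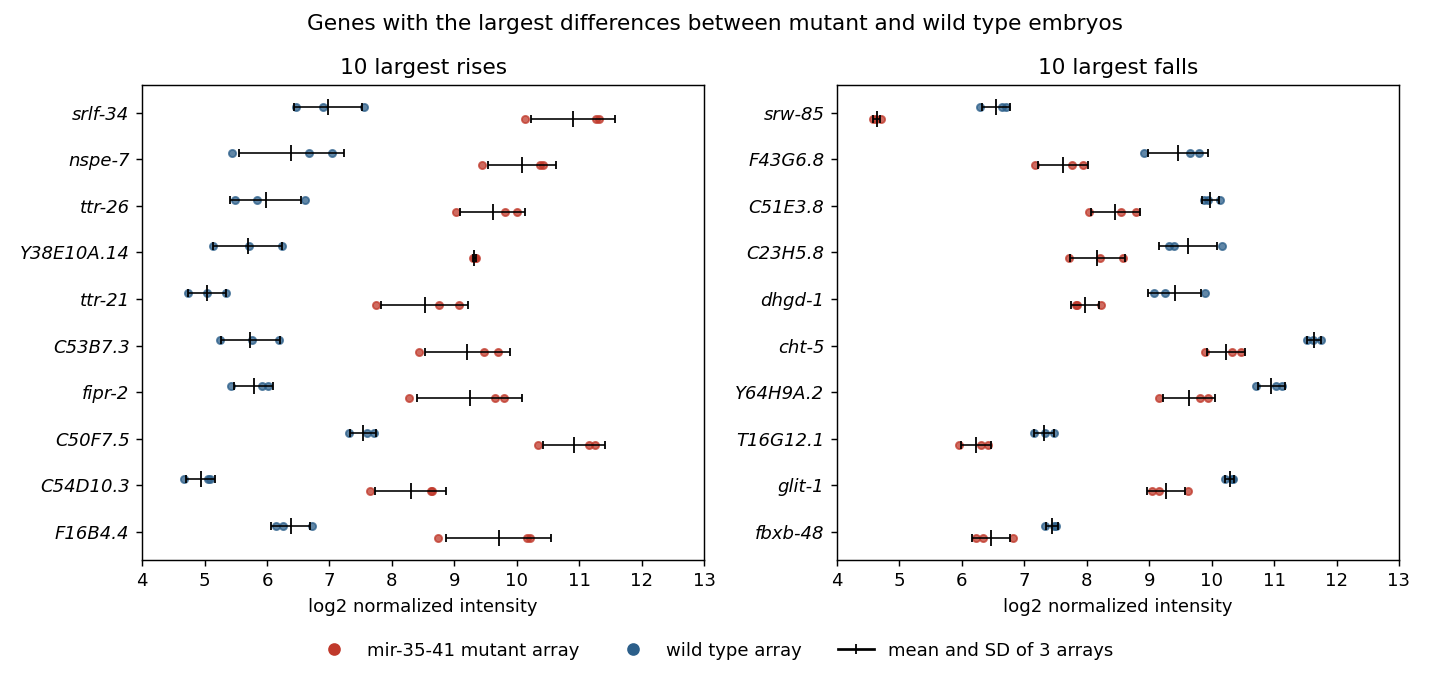
Log2 normalized intensity (horizontal axis) of the 10 genes with the largest rises (left) and the 10 with the largest falls (right) among genes past the threshold, with 1 point per array in red for the mutant and blue for wild type, and the mean and SD of 3 arrays in black. The genes were chosen among those whose groups do not overlap, and their rises run from 3.93 for srlf-34 to 3.33 for F16B4.4 and their falls from -1.91 for srw-85 to -0.97 for fbxb-48.

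All 637 genes had groups of arrays that did not overlap, which a call with 3 arrays per group nearly requires. This held for 24.4% of all genes measured, against an expected 10% for interchangeable arrays. Genes are correlated, so the share in any 1 split can lie far from 10%, and it was not computed for other splits. The count of genes depended strongly on single arrays. It was 1971 without mutant replicate 1, 127 without mutant replicate 2 and 84 without mutant replicate 3, and 423, 130 and 231 without wild type replicates 1, 2 and 3. The falls among these numbered 724, 4 and 5, and 77, 14 and 16.

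The second question was whether transcripts tied to the mir-35 family in earlier work were higher without the microRNAs. The deleted microRNAs have no probe sets on the array, so the deletion itself was not checked by these data. Of the genes listed for the locus, only mdt-8, a subunit gene of the Mediator complex, was measured, with a difference of -0.35 (SE 0.10, n = 3 against 3, limma adjusted p = 0.13). Its 95% interval, not adjusted for the number of genes, ran from -0.59 to -0.10, and its other probe set gave -0.40. None of the 5 measured genes tied to the family passed the threshold with limma, and none had an unadjusted p under 0.05. For nhl-2, which encodes a cofactor of the microRNA complex, the difference was -0.09, with a 95% interval from -0.44 to 0.26. For sup-26, an RNA-binding regulator of sex determination, it was 0.07, with an interval from -0.37 to 0.51. The cell death activator egl-1 differed by 0.02 (interval -0.21 to 0.25), the translational repressor gld-1 by -0.04 (interval -0.38 to 0.31) and the F-box gene lin-23 by -0.00 (interval -0.20 to 0.20). These intervals leave room for rises of up to 1.20-fold for nhl-2, 1.43-fold for sup-26, 1.19-fold for egl-1, 1.24-fold for gld-1 and 1.15-fold for lin-23. They cover only the spread between these arrays. A difference in embryo stages between the groups, which they do not cover, could hide a larger rise. Each of these 5 differences changed sign when some single array was left out. The other probe sets of gld-1 and lin-23 gave -0.28 and -0.01. The arrays measured messenger RNA, so a change in protein alone would not be seen.

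The third question was which groups of genes moved together, over 26 lists fixed before the data were examined. Innate immune genes made up the list with the largest median difference, at 0.74 on the log2 scale, or 1.67-fold. Of its 21 measured members 6 rose and none fell, and 18 were higher when adjusted over the list alone. The antimicrobial peptide gene cnc-4 rose by 3.32 (SE 0.26, limma adjusted p = 0.00409), nlp-29, an antimicrobial peptide gene of the epidermis, by 2.75, the lysozyme gene lys-7 by 2.56 and the pathogen response gene C17H12.8 by 1.79. The probe sets of nlp-29 and lys-7 are of the kinds shared between transcripts. The list as a whole shifted up (camera adjusted p = 2.08e-12), a call that was lost with an estimated correlation (adjusted p = 0.729). The median of this list was 0.53 and 0.52 above the mean of the 6 arrays on mutant replicates 2 and 3 and -0.04 on mutant replicate 1, and lay between -0.60 and -0.24 on the wild type arrays.

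Detoxification genes held 3 rises among 26 measured members, and 9 members were higher when adjusted over the list alone. The metallothionein gene mtl-1 rose by 2.89 (SE 0.24, limma adjusted p = 0.00409), the cytochrome P450 gene cyp-13A5 by 1.52 and sod-3, a mitochondrial superoxide dismutase gene, by 1.34. The wild type means of mtl-1 and cyp-13A5, 5.11 and 4.70, lay within the range of the yeast control probe sets, so these 2 differences are at best lower bounds. The list shifted up with a median of 0.08 (camera adjusted p = 0.00144, and adjusted p = 0.729 with an estimated correlation), and the median was 0.01 after median centring. Among 32 genes of lipid metabolism, the desaturase genes fat-2, fat-6 and fat-1 rose by 1.79, 1.65 and 0.66, 3 members also rose when adjusted over the list alone, and the list had a median of 0.02 (camera adjusted p = 0.0966). Of 25 intestinal genes 2 rose, mtl-1 and fat-6, as they did when adjusted over the list alone, with a list median of 0.06 (camera adjusted p = 0.0966). The lists of lipid metabolism and intestine had medians of -0.04 and -0.01 after median centring, with which the intestinal list passed. Without wild type replicate 1 both lists passed, with medians of 0.10 and 0.19.

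Cuticle genes of late embryos moved in both directions. Of 25 measured members 5 collagen genes rose over all genes, and 9 rose and 4 fell when adjusted over the list alone. The collagen genes dpy-9, dpy-5, rol-6 and dpy-8 rose by 2.03, 1.90, 1.16 and 0.89, with adjusted p-values from 0.00266 to 0.0143. The list median was -0.09 and its mean 0.24, so the signs differ, and the list did not pass (camera adjusted p = 0.227, direction up). Among 22 epidermal genes che-14 and elt-3, a GATA factor of the epidermis, fell by 0.66 and 0.60, over all genes and adjusted over the list alone alike, with a list median of -0.09 (camera adjusted p = 0.195).

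Among 30 measured neuronal genes egl-3 and egl-21, which encode enzymes that process neuropeptide precursors, rose by 1.52 (SE 0.25, limma adjusted p = 0.0279) and 1.42, and the tubulin gene tbb-4 fell by 0.70. These 3 also passed when adjusted over the list alone, and the list median was 0.14 (camera adjusted p = 0.229). No member of the body wall muscle list (23 measured, median 0.03, camera adjusted p = 0.771) or of the pharynx list (16 measured, median 0.09, camera adjusted p = 0.0663) passed, over all genes or over the list alone. Without mutant replicate 1 the neuronal and pharynx lists passed, with medians of 0.20 and 0.18, and the pharynx list also passed after median centring, with a median of 0.02. The neuronal median was -0.04 without wild type replicate 1. The largest differences of these muscle and pharynx genes were 1.04 for unc-89 and 0.94 for tnt-2 in muscle, and 1.49 for myo-2 and 1.48 for myo-1 in the pharynx, with SEs of 0.38, 0.21, 0.39 and 0.37. The value for unc-89 is that of the brightest of 5 probe sets, and the other 4 gave 0.25, -0.01, 0.27 and 0.31.

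Transcripts of early embryos had lower medians in the mutant. The list of first zygotic transcripts had a median of -0.28 over 24 members (camera adjusted p = 0.00385) and the list of maternally loaded transcripts -0.26 over 30 members (camera adjusted p = 0.012). With an estimated correlation each of these had an adjusted p = 0.914, and no single member passed, over all genes or over the list alone. The largest differences were -0.91 for cpg-2 and -0.55 for puf-3 among maternal transcripts, and -0.82 for sdz-38 and -0.74 for pes-10 among zygotic ones. These lists did not separate the groups on every array. Relative to the mean over the 6 arrays, the zygotic median was 0.16 on mutant replicate 1 against -0.32 and -0.30 on mutant replicates 2 and 3, and 0.30, 0.08 and 0.09 on the wild type arrays. The zygotic list had a median of -0.48 without mutant replicate 1 and an adjusted p = 0.0539 without mutant replicate 2. The maternal list had adjusted p-values of 0.0908 without mutant replicate 2, 0.0715 without mutant replicate 3, 0.0796 without wild type replicate 1, 0.0736 without wild type replicate 2 and 0.0691 without the dimmest 50% of probe sets. Its median was -0.16 without mutant replicate 3.

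**Figure D2:**
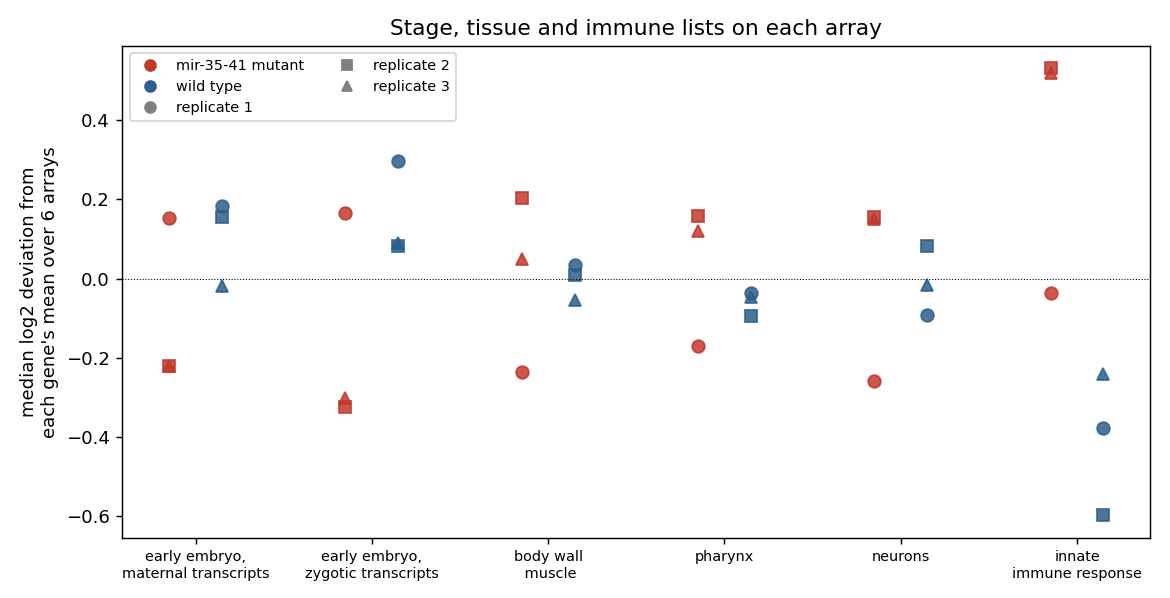
Median deviation of 6 gene lists on each array, in log2 units relative to each gene's mean over the 6 arrays (vertical axis), with red for mutant, blue for wild type and marker shape for the replicate number. Mutant replicate 1 lies at 0.15 and 0.16 for the early embryo lists, where mutant replicates 2 and 3 lie between -0.32 and -0.22, and it lies below all other arrays for muscle, pharynx and neurons.

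Patterning and germline genes were lower as lists. The list of Hox, homeobox and related patterning factors had a median of -0.25 over 20 members (camera adjusted p = 6.56e-04, and adjusted p = 0.729 with an estimated correlation), and 7 members were lower when adjusted over the list alone. Over all genes 1 member fell, lin-32, a proneural factor of the basic helix-loop-helix class, at -0.93 (SE 0.17, limma adjusted p = 0.0349). The germline list had a median of -0.17 over 28 members (camera adjusted p = 0.0179, and adjusted p = 0.914 with an estimated correlation). Its 1 fall, also adjusted over the list alone, was that of pgl-3, a P granule component, at -0.70 (SE 0.08, limma adjusted p = 0.00908). The germline list had adjusted p-values of 0.208, 0.0966 and 0.0616 without mutant replicate 2, wild type replicate 1 and wild type replicate 2, and 0.105 without the dimmest 50% of probe sets. Its median was -0.38 and -0.11 without mutant replicates 1 and 2, -0.27 without wild type replicate 3 and -0.28 with array weights. Relative to the mean of the 6 arrays, the germline median was 0.09 on mutant replicate 1, among the wild type arrays at 0.13, 0.12 and -0.00, against -0.32 and -0.13 on mutant replicates 2 and 3.

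The spermatogenesis list held 4 rises among 38 measured members, all of them major sperm protein (msp) genes, whose near-identical copies share probes and are reported only as a family. Adjusted over the list alone, 9 members were higher and 2 lower. The list median was 0.06 (camera adjusted p = 0.00374, and adjusted p = 0.914 with an estimated correlation). After quantile normalization 1 msp gene was higher, and the list had an adjusted p = 0.063 and a median of 0.02, and the median was -0.01 after median centring. It was 0.14 without mutant replicate 3, 0.04 and 0.09 without wild type replicates 2 and 3, and 0.15 and 0.21 without the dimmest 25% and 50% of probe sets. Outside the msp family the largest differences were -0.60 for spe-44 and 0.38 for spe-10, neither past the threshold and both dim, within the range of the yeast control probe sets in wild type. Among 16 yolk and adult cuticle genes vit-1, a yolk protein gene, rose by 0.58 (SE 0.11, limma adjusted p = 0.0426), also when adjusted over the list alone, and the list median was 0.00 (camera adjusted p = 0.393). The call of vit-1 was kept in 1 of the 6 fits without 1 array, that without mutant replicate 1, and was lost with the replicate block, quantile normalization, median centring and the pseudocount of 16, with differences between 0.46 and 0.64 in all of these.

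Other groups held few calls or none. Of 16 cell death genes cps-6, which encodes a mitochondrial endonuclease, and ced-7, an engulfment gene, rose by 1.06 and 0.65, and 3 rose and 1 fell when adjusted over the list alone, with a median of -0.06 and a camera direction of up (adjusted p = 0.767). Of 16 histone genes the linker histone gene hil-1 rose by 1.05, over all genes and over the list alone (list median -0.13, camera adjusted p = 0.62). Of 16 heat shock genes the mitochondrial chaperonin gene hsp-60 fell by 0.95 (SE 0.12, limma adjusted p = 0.011), again on either adjustment (list median -0.06, camera adjusted p = 0.801).

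No member passed, over all genes or over the list alone, in the following 8 lists. The cell cycle list had a median of -0.16 (27 measured, camera adjusted p = 0.0663), with cdk-4 at -0.70 (adjusted p = 0.0504) and rnr-2 at -0.43. The list of DREAM complex and Rb pathway genes had a median of -0.23 (12 measured, camera adjusted p = 0.117), with lin-54 at -0.40 and efl-1 at -0.33. Small RNA machinery had a median of -0.13 (28 measured, camera adjusted p = 0.637), with prg-1 at 0.63 and hrde-1 at -0.57. Ribosomal protein genes had a median of 0.03 (57 measured, camera adjusted p = 0.108), with rps-6 at 0.12 and rps-21 at 0.11. Without mutant replicate 1 the cell cycle and DREAM lists passed, with medians of -0.33 and -0.40. Without wild type replicate 3 these 2 and the ribosomal list passed, with medians of -0.21, -0.24 and 0.09. The dosage compensation list had a median of 0.06 (9 measured, camera adjusted p = 0.642), with sdc-2 at 0.33 and sdc-3 at 0.31. The sex determination lists had medians of 0.06 for genes listed as male-promoting (11 measured, mean -0.00, camera adjusted p = 0.642) and -0.09 for hermaphrodite-promoting genes (12 measured, camera adjusted p = 0.828). In the former list fox-1 differed by -0.33 and fem-1 by 0.33. As fox-1 promotes hermaphrodite development, its place there is an error of the list, whose median is not one of male-promoting genes alone. The earlier targets above had a list median of -0.00 (camera adjusted p = 0.828, direction up).

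**Figure D3:**
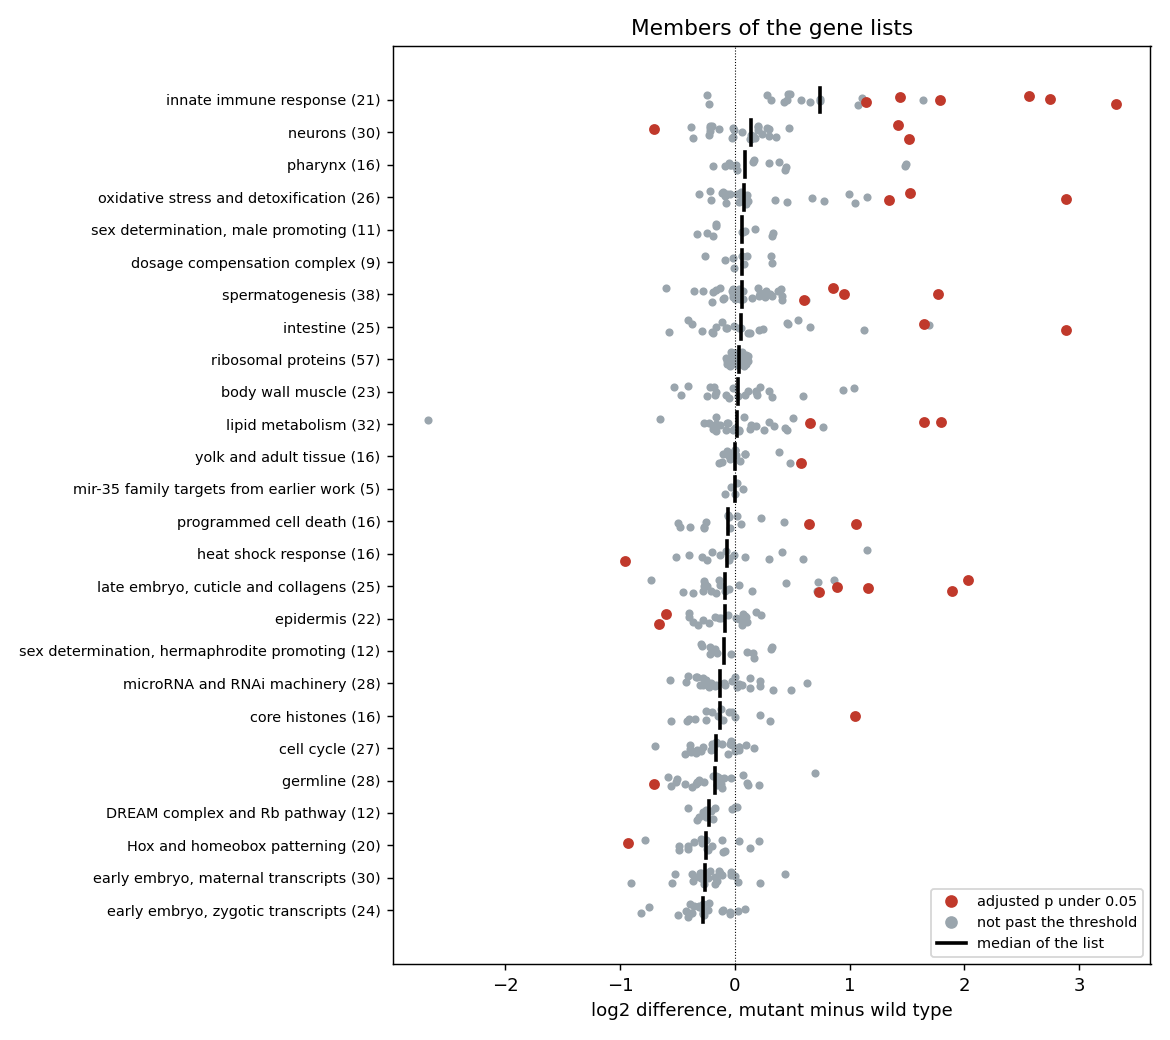
Log2 difference, mutant minus wild type (horizontal axis), of each measured member of 26 gene lists (rows, with the number measured), in red where the adjusted p over all genes was under 0.05 and in grey otherwise, with a black bar at each list's median. The innate immune list has the highest median, 0.74, and the early zygotic list the lowest, -0.28.

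The last question was whether X-linked genes differed from autosomal genes as a class, since earlier work ties the mir-35 family to sex determination. The median difference was -0.02 over 2356 X-linked genes and -0.05 over 14476 autosomal genes, a gap of 0.03 on the log2 scale that did not pass (camera p = 0.16, and p = 0.515 with an estimated correlation). Of X-linked genes 90 rose and 16 fell, or 3.82% and 0.679%, against 434 and 95 autosomal genes, or 3.00% and 0.656%. Leaving out the array of mutant replicate 1 gave a gap of 0.05, which passed the threshold with camera at the preset correlation.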

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

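The setting without both arrays numbered 1 was chosen after the data were seen; the other settings were planned. The planned seed match test and its alternatives were not run, for lack of sequences. Median centring and quantile normalization kept 583 and 602 of the 637 genes. Median centring moved the median difference of all probe sets from -0.05 to -0.11. Counts of probe sets and genes stayed within 1.5 times under quantile normalization, median centring, the filter on the dimmest 25%, the pseudocount of 16 and the intensity trend with robust fit. Single arrays moved the counts strongly. Left out in turn, they gave 109 to 2404 probe sets, 84 to 1971 genes, 4 to 11 gene lists and an X-to-autosome gap of 0.0156 to 0.0467. The count rose without mutant replicate 1, which had the lowest array weight, 0.334. Fewer arrays also lower the power of the test, and this was not separated from the effect of each array. Of the 46 named genes past the threshold, 13 to 46 kept their call when 1 array was left out. The calls of C23H5.8, glit-1, fbxb-48, che-14, elt-3, lin-32, fat-1, egl-3, tbb-4, ced-7 and vit-1 were kept in 1 of these 6 fits. Those of srlf-34, ttr-26, Y38E10A.14, ttr-21, C50F7.5, C54D10.3, srw-85, cnc-4, mtl-1 and dpy-9 were kept in all 6, and the remaining calls lay in between. Dim signal also limits the calls. Of the 525 rises, 121 had wild type means within the level of the yeast control probe sets, and 25 of these also mutant means. Of the 112 falls, 2 had mutant means within that level. Of the 637 genes, 394 were among the brighter 50% of probe sets.

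The replicate number was not taken to pair the samples, since no label says so and the correlation of deviations was over 0.1 for number 1 alone, at 0.199 against 0.0165 and 0.0897. Mutant arrays 1 and 2 correlated best with the wild type array of their own number, and mutant array 3 with that of number 2 (0.345). In the second principal component the arrays numbered 1 lay apart, at 19.2 and 25.6 against -21.1 to -3.07 for the other 4, so a shared factor of number 1 is not excluded. With the replicate block, 882 probe sets, 783 genes and 9 lists passed, with 514 of the genes shared, and the X-to-autosome gap stayed at 0.0344.

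Further counts that moved were as follows, and the cause was not tested. In some of these settings fewer probe sets or arrays entered. Without the dimmest 50% of probe sets, 470 probe sets and 407 genes passed. Array weights gave 4195 probe sets, 3392 genes (1782 higher and 1610 lower) and 12 lists. The X-to-autosome gap was then 0.0420 and passed the threshold with camera at the preset correlation, as it did without mutant replicate 1. Requiring at least 2-fold left 413 probe sets and 341 genes. The plain equal-variance test left 1 probe set and 0 genes, so none of the 46 named calls passed with it. No list passed with an estimated correlation (0) or with the directional test of fry (0), though at the preset correlation 7 did. Before adjustment 1 list was under 0.05 with limma's camera at an estimated correlation (Hox and homeobox) and 3 were with limma's directional fry (Hox and homeobox, innate immune and detoxification). The mixed test of fry ignores direction. Of the 7 lists it did not pass the early zygotic and maternal ones (fry mixed adjusted p = 0.115 and 0.171). It passed the others (fry mixed adjusted p from 7.79e-04 to 0.00989), and also some lists that camera did not, such as lipid metabolism (fry mixed adjusted p = 2.09e-04). Without both arrays numbered 1, 3508 probe sets, 2997 genes (1597 higher and 1400 lower) and 13 lists passed. Lists that passed only in other settings were cell cycle and pharynx with the replicate block; cell cycle, intestine and pharynx with the intensity trend; these 3, DREAM and ribosomal proteins with array weights; and cell cycle, DREAM, intestine, pharynx, neurons and late cuticle without both arrays numbered 1. The X-to-autosome gap was then 0.0612 and passed at the preset correlation. In none of the settings where this gap passed was it tested with an estimated correlation.

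Values that changed sign belonged to 12 lists and 7 genes, of which the spermatogenesis list alone had passed. Under median centring the list medians were -0.0394 for body wall muscle, -0.0025 for dosage compensation, -0.0089 for intestine, -0.0432 for lipid metabolism, -0.0305 for ribosomal proteins, -0.0011 for male-promoting sex determination, -0.0064 for spermatogenesis and -0.0626 for yolk and adult tissue, and egl-1 differed by -0.0438. Quantile normalization gave -0.0309 for yolk and adult tissue, -0.0050 for egl-1 and 0.0376 for lin-23. Without the dimmest 50%, lipid metabolism was at -0.0043 and the earlier targets at 0.0106. Array weights gave -0.0465 for dosage compensation, 0.0418 for heat shock and -0.0456 for sdc-2. Without both arrays numbered 1, dosage compensation was at -0.0861, epidermis at 0.0405, heat shock at 0.0225, the earlier targets at 0.0039, nhl-2 at 0.0046 and sdc-2 at -0.2658. With each array left out in turn, medians ranged from -0.0547 to 0.1151 for dosage compensation, -0.1378 to 0.0143 for epidermis, -0.1185 to 0.1194 for male-promoting sex determination, -0.0162 to 0.1049 for lipid metabolism, -0.1185 to 0.0528 for the earlier targets, -0.0597 to 0.0718 for yolk and adult tissue, -0.0402 to 0.2026 for neurons and -0.0522 to 0.0866 for body wall muscle. Single genes ranged from -0.0420 to 0.0775 for egl-1, -0.0411 to 0.0311 for lin-23, -0.1764 to 0.0528 for gld-1, -0.1907 to 0.0623 for nhl-2, -0.2184 to 0.7758 for sdc-2, -0.0111 to 0.2254 for rps-21 and -0.1185 to 0.2585 for sup-26. The cause of these changes was not tested.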

Other observations

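All families, gene ontology terms and tests of explanations in this part were chosen after the results were seen. Genes named here fall outside the rule for named genes unless the report names them. Among 168 gene families formed by the stem of the gene name, 4 were enriched for rises and 1 for falls past the threshold (1-sided tests against all genes, Benjamini-Hochberg adjusted). These tests treat genes as independent, and none of these families passed camera with an estimated correlation (camera adjusted p = 0.919 for each). Of 60 neuropeptide-like (nlp) genes 9 rose, with nlp-29 at 2.75, nlp-30 at 2.12 and nlp-27 at 1.96 (enrichment adjusted p = 0.00628). Of 41 transthyretin-like (ttr) genes 9 rose, among them ttr-15 at 3.15 and ttr-23 at 2.90, at best a lower bound since its wild type mean of 4.31 lay at the level of the yeast control probe sets (enrichment adjusted p = 4.96e-04). Of 12 galectin (lec) genes 4 rose, led by lec-6 at 1.90, and of 33 astacin-type protease (nas) genes 6 rose, led by nas-11 at 2.11 (enrichment adjusted p = 0.0174 for each). The gtnt family held 5 falls among 55 genes (enrichment adjusted p = 0.00465). Several members of these families have near-identical copies, so a probe set may read more than 1 of them, and the 9 rises of the nlp family are then fewer than 9 independent results. With median centring 10 nlp, 12 ttr, 5 lec and 6 nas genes were higher and 6 gtnt genes lower, against 9, 9, 4, 6 and 5 as deposited.

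Among 253 gene ontology process terms, 4 were enriched for rises past the threshold and none for falls. Of 50 genes of neuropeptide signalling 10 rose (enrichment adjusted p = 5.20e-04), of 12 genes of defence against fungus 4 rose and of 124 genes of lipid metabolism 12 rose (enrichment adjusted p = 0.0244 for each), and of 14 genes of a term on proteolysis in protein breakdown 5 rose (enrichment adjusted p = 0.00504). No family or term passed camera with an estimated correlation. The terms may share members with the families and lists, as the nlp family shares nlp-29 with the innate immune list. Their rises are therefore not to be read as separate results. Of 96 F-box B (fbxb) genes 2 fell and none rose, and 2 of the 96 had a positive difference, with a median of -0.42, or -0.49 after median centring. The largest difference of a listed gene that did not pass was that of acdh-1, an acyl-CoA dehydrogenase gene, at -2.67 (limma adjusted p = 0.244), whose arrays had SDs of 1.92 in the mutant and 1.58 in wild type.

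The rise of 525 genes has several candidate explanations. A lower share of early embryos in the mutant preparations was tested by adding to the fit a score for each array from the early embryo lists. The median difference of these genes was then 1.02 against 1.20 without the score, with a median SE of 0.16. All 525 stayed positive and 290 kept their call. The genes were chosen on these same arrays, and the score is an imperfect measure made from them, so the fit cannot decide for or against this explanation. The score was 0.16 on mutant replicate 1, -0.27 and -0.26 on mutant replicates 2 and 3, and 0.04 to 0.24 on the wild type arrays. Adult hermaphrodite tissue is argued against, since hypochlorite dissolves adults and adult tissue should bring its abundant yolk protein messages. The median difference of the yolk and adult cuticle list was 0.0028, with fat-7 as the 1 member shared with the lipid and intestinal lists. It was 0.0499 over the 11 of its 16 members brighter than the yeast control probe sets. Among these, vit-3 and vit-6 had mean log2 intensities of 6.73 and 6.07 in the mutant and 6.73 and 6.11 in wild type. However, vit-1 rose by 0.58, a call kept in 1 of 6 fits without 1 array. The msp family of sperm genes also went the other way, with 22 of 23 genes positive, a median of 0.27 and 4 rises. A small share of sperm-bearing tissue is therefore not excluded. A larger share of embryos at the end of embryogenesis, or of hatched larvae, cannot be told apart from a change within embryos. The late cuticle list had a median difference of -0.0856 with 11 of 25 members above 0 and 5 rises. However, 4 probe sets of list members left out as shared with other genes were all positive, up to 1.85 for that of sqt-2 (limma adjusted p = 0.0104). The loss of the microRNAs itself stays open as an untested biological explanation. Each group was 1 strain, so that loss cannot be told apart from any other difference between the strains.

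Mutant replicate 1 stood apart from mutant replicates 2 and 3 in the first principal component (-8.33 against -39.3 and -36.2). Its correlations with them were 0.989 and 0.991, against 0.998 between the others. Pairs of wild type arrays correlated at 0.991, 0.989 and 0.994. The correlations of mutant replicate 1 were thus not unusual, and the closeness of mutant replicates 2 and 3 was the exception. A candidate explanation is more early embryos in the preparation of mutant replicate 1. Its early embryo score lay 0.426 above the mean of the other mutants, and its neuron, pharynx and muscle medians lay below theirs at -0.26, -0.17 and -0.23. Wild type replicate 1 also had the highest score of its group (0.24 against 0.12 and 0.04). These values had been seen before the test was set, and no other explanation was tested, so a difference of handling stays open.

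Other splits of the 6 arrays into 3 and 3 number 10 with the real one, and 1 of them, the real one, gave as many calls as it did. It gave 785 probe sets and 637 genes, and the highest of the others gave 0. In those others each group mixed mutant and wild type arrays, so any difference between them added to the spread within groups. The 0 is therefore not a chance level for the real split. With 10 splits a share under 0.05 cannot be reached.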
